A study of Homo sapiens with 10 samples.

How the data were processed

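The series holds 10 ChIP-seq libraries of HCT116 cells, an established human colorectal carcinoma line, with 1 library per antibody. The peak lists of 5 of them were analysed: total RNA polymerase II (Pol II, an antibody to its N-terminal part per the labels), KAP1 (the TRIM28 protein, a chromatin-bound co-regulator), Larp7 and Hexim1 (proteins of the 7SK small nuclear ribonucleoprotein, which holds the kinase P-TEFb inactive), and Cdk9 (the kinase subunit of P-TEFb). The libraries labelled Ser5P Pol II, H3K4me3, H3K4me1, H3K27ac and Input were not analysed here. Per the labels' protocols, cells were crosslinked with 1% formaldehyde for 10 min and chromatin was sonicated for 50 min to fragments of 100 to 300 bp before immunoprecipitation. The labels give the cell type of this line as endothelial, and the line itself is of epithelial origin.

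Per the submitters' processing notes, reads were aligned with Bowtie 1.1 to hg19 and peaks were called with MACS2, with no version given. The control library, the treatment of duplicate reads, the read depth and the calling settings are not given in the sources used here. Each list belongs to 1 sample, and no pooling of libraries is named in the sources used here. The Pol II list is in the narrow peak layout and the other lists are in the broad peak layout. The deposited fold in column 7 is the authors' ratio of a peak over its background. It was used to describe, rank or split peaks and promoters within their own list, and for the ratio of chromosome X to chromosomes 1 to 22 within each list. The folds themselves were not compared between lists. Columns 8 and 9 hold the −log10 of the p and of the q of each peak as deposited. The deposited score in column 5 was not used. Coordinates are those of hg19 (GRCh37), written 1-based. No peak ended past the end of a chromosome of the GRCh37 reference, and the smallest gap to an end was between 10418 and 10537 bp over the 5 lists. Peaks on chromosomes 1 to 22, X and Y were kept, which left out 2 Cdk9 peaks on other sequences.

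Genes were taken from the GENCODE release 44 annotation on GRCh37. Each of 20136 protein-coding gene symbols had 1 promoter, the annotated 5′ end of the gene and 1 kb on each side, and a factor was counted at a promoter when a peak overlapped this window by at least 1 bp. The gene body ran from 2 kb past the 5′ end to the 3′ end in genes of at least 4 kb. A peak was placed by its middle, first at a coding promoter, then in an exon, an intron or between genes.

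Overlap between lists was counted at 1 bp or more. Shares carry an exact (Clopper-Pearson) 95% binomial interval, which covers counting error only. Chance overlap was taken from 1000 circular shifts of a list within each chromosome by at least 1 Mb, and from 100 such shifts for the places of peaks. Differences between shares carry a 95% interval from 1000 bootstraps of 10 Mb genome blocks. With 1 library per antibody there is no replicate check on any value, and no p-value across peaks or genes is given. Neither the percentiles nor the intervals say how a second culture would behave. Read depth per library is unknown, so lists of different length were also compared at a stricter threshold and at equal length.

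Before the data were examined, 14 results, 79 alternatives and 19 gene lists were fixed. The lists were immediate early, NF-kB inducible, heat shock and chaperone, p53 targets, Wnt targets, transcription elongation, 7SK snRNP and KAP1, cell cycle, glycolysis, imprinted, colon epithelium, endothelium, fibroblast and smooth muscle, blood cells, other tissues, ribosomal protein, zinc finger (ZNF), replication-dependent histone, and snRNA, which holds spliceosomal genes and the U7 gene. Each of the 18 lists of coding genes was compared with 10000 random lists of as many coding genes, and within Pol II promoters with 10000 random lists of as many Pol II promoters where it had at least 5 of these. The random lists were not matched for Pol II fold. A percentile among random lists describes these libraries. Older symbols were matched through a RefSeq table, which changed CYR61, CTGF and IL8 to CCN1, CCN2 and CXCL8, and PECAM1 was not matched.

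The rule for named genes took the 12 genes of highest KAP1 fold among promoters with all 5 factors, the 6 of highest Pol II fold among Pol II promoters without KAP1, the 6 of highest KAP1 fold among KAP1 promoters without Pol II, the 4 members of highest KAP1 fold of each list, and the genes of the factors and the 7SK RNA. It also took the 8 KAP1 peaks and the 3 peaks of each other list with the highest −log10 p. Other genes named were chosen after their values were seen, which is said where they appear. Some genes that the rule takes are not reported here.

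The alternatives were peaks with a −log10 q of at least 5, the 20000 peaks of highest −log10 p of each list, peaks within 1 kb merged, overlap of at least 50% of the shorter peak, every peak replaced by its middle and 250 bp on each side, shifts of 50 to 200 kb, promoter windows of 500 bp and 2 kb, the start of any annotated transcript, and strata of KAP1 peak width or gene length. A further 24 alternatives were added after the data were seen, 16 of them within deciles of Pol II fold or promoter GC content for ribosomal protein and histone genes. The functions were tested on simulated data. A list of 59960 peaks placed at random on the genome overlapped an unrelated list 0.969 times as often as after shifts. Both lists were placed at random within each chromosome, so the shifts were not tested on lists that cluster in the same regions. A simulated difference was inside its interval in 95.5% of 200 runs. A difference of 9.92 points that came only from strata averaged -0.0171 within them, where the interval held 0 in 92.0% of runs. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.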

Results

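Peak lists of 5 ChIP-seq libraries from HCT116 colorectal carcinoma cells were analysed, 1 for each of total Pol II, KAP1, Larp7, Hexim1 and Cdk9, out of 10 libraries in the series. The design concerns KAP1, the 7SK ribonucleoprotein and Pol II at human genes, so the comparisons ask which of these factors share sites and at which genes. The Pol II list held 92939 peaks with a median width of 287 bp, and KAP1 had 61312 peaks with a median width of 513 bp. Larp7 had 184243 peaks, Hexim1 had 229679 and Cdk9 had 120113, with median widths of 471, 453 and 427 bp. Together the peaks covered 1.35% of the genome for Pol II, 1.48% for KAP1, 4.73% for Larp7, 6.02% for Hexim1 and 2.54% for Cdk9. The lists differed in the deposited q of their peaks. A −log10 q of at least 5 was reached by 75.4% of Pol II peaks, 20.0% of Hexim1 peaks, 18.5% of Larp7 peaks, 14.0% of KAP1 peaks and 4.42% of Cdk9 peaks. Read depth is unknown and the Pol II list has another peak layout, so these shares do not rank the lists by strength. No library had a replicate, so the values describe these libraries.

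KAP1 sites were shared with all of the other factors. Larp7 overlapped 55742 of the 61312 KAP1 peaks (90.9%, exact 95% interval 90.7 to 91.1), and Hexim1 overlapped 93.0% (92.8 to 93.2). Cdk9 overlapped 76.3% of them (76.0 to 76.7) and Pol II overlapped 64.2% (63.9 to 64.6). When the KAP1 list was shifted along the chromosomes, these shares averaged 11.9% for Larp7, 14.8% for Hexim1, 7.13% for Cdk9 and 4.33% for Pol II. The observed overlap was thus 7.67 times the shifted one for Larp7, 6.27 times for Hexim1, 10.7 times for Cdk9 and 14.8 times for Pol II, and 0 of 1000 shifts reached the observed overlap for any of the 4 lists. With shifts of only 50 to 200 kb the ratios were 3.23, 2.81, 4.10 and 4.90. The Cdk9 share fell to 30.2% among peaks with a −log10 q of at least 5, where 5307 Cdk9 peaks were left. With 20000 peaks per list the Larp7 share was 52.7% and the Hexim1 share 61.0%.

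**Figure D1:**
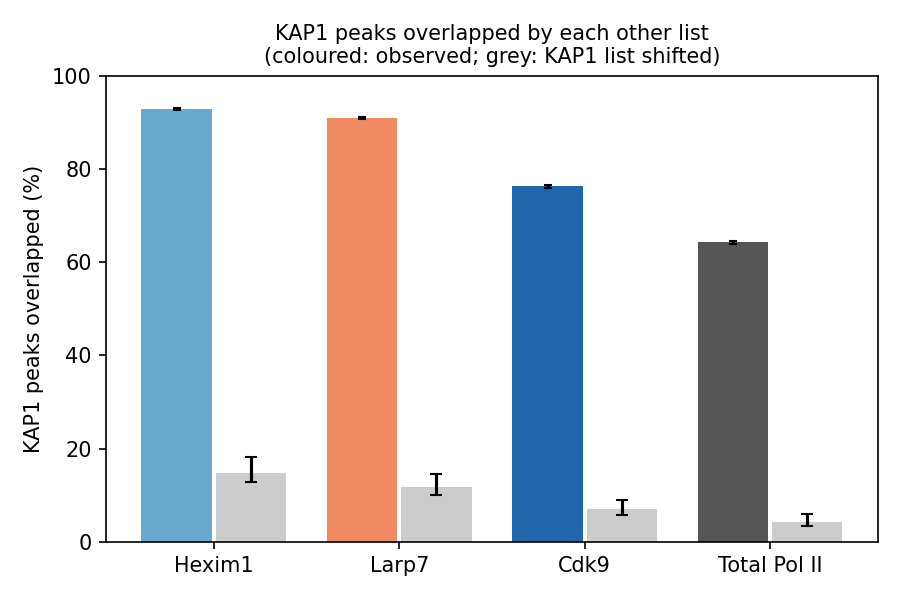
Share of the 61312 KAP1 peaks (vertical axis, percent) overlapped by at least 1 bp by each other list. Coloured bars are observed shares with exact 95% intervals, and grey bars are the mean over 1000 shifts of the KAP1 list with their lowest and highest values. Observed shares run from 64.2% for Pol II to 93.0% for Hexim1, and shifted means from 4.33% to 14.8%.

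The sharing was uneven between the lists. KAP1 overlapped 59.2% of Pol II peaks (58.9 to 59.5) and 37.8% of Cdk9 peaks, but only 26.2% of Larp7 peaks and 21.1% of Hexim1 peaks. Pol II peaks were overlapped by Hexim1 in 88.5% of cases, by Larp7 in 82.5% and by Cdk9 in 68.2%. In turn, Pol II was present at 36.9% of Cdk9 peaks, 25.5% of Larp7 peaks and 21.4% of Hexim1 peaks. Among peaks with a −log10 q of at least 5, KAP1 overlapped 12.4% of Pol II peaks.

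Most KAP1 sites carried Larp7, Hexim1 and Cdk9 together, and Pol II was mostly at those sites. The 3 factors were all present at 45787 KAP1 peaks (74.7%, 74.3 to 75.0), and all 3 together with Pol II at 36409 (59.4%, 59.0 to 59.8). Pol II overlapped 79.5% of the KAP1 peaks with all 3 factors. It overlapped 29.8% of the 8611 peaks with Larp7 and Hexim1 but no Cdk9, 8.84% of the 2092 with Hexim1 alone, 4.31% of the 1091 with Larp7 alone and 1.77% of the 2717 with none of them. KAP1 peaks with all 3 factors had Pol II more often than the other KAP1 peaks by 60.3 percentage points (block bootstrap 95% interval 59.2 to 61.6). They were also wider, at a median of 621 bp, against 227 bp for those with no other factor; within deciles of KAP1 peak width the difference was 47.3 points. The share with all 3 factors was 27.5% among peaks with a −log10 q of at least 5, 29.4% with 20000 peaks per list and 42.4% with every peak replaced by its middle and 250 bp on each side, and the Pol II difference was then 15.5, 32.2 and 27.1 points.

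Strong KAP1 peaks lay almost entirely within the other lists. In the decile of KAP1 peaks with the highest fold, 99.6% had Larp7, 99.7% Hexim1 and 90.8% Pol II, and the interval for Cdk9 was 94.4% to 95.5%. In the decile with the lowest fold the shares were 70.1% for Larp7, 78.9% for Hexim1, 27.8% for Pol II and 42.2% for Cdk9. Seen from Pol II, KAP1 was present at 94.5% of the decile of Pol II peaks with the highest fold and at 34.4% of the decile with the lowest. Peaks of higher fold were also wider, and a wider peak is more easily overlapped by 1 bp. Median widths in the highest and lowest deciles were 626 and 416 bp for KAP1, and 1018 and 190 bp for Pol II. Fold and width were not separated here.

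As a share of their own peaks, KAP1 and Pol II were the most often at promoters, but the lists differ in length. The middle of 10840 KAP1 peaks (17.7%, 17.4 to 18.0) lay within 1 kb of a coding gene's 5′ end, 11.5 times the share after shifts. Pol II followed with 16.7% (10.3 times), then Cdk9 with 9.62% (6.52 times), Larp7 with 6.48% (4.53 times) and Hexim1 with 5.29% (3.75 times), whose longer list has more promoter peaks than KAP1, 12145. With 20000 peaks per list, Hexim1 was at 52.9% of coding promoters, Pol II at 53.9% and KAP1 at 41.4%. Outside promoters, 15.9% of KAP1 peaks lay in exons, 35.1% in introns and 31.3% between coding genes. Promoter KAP1 peaks overlapped Pol II in 94.3% of cases, Cdk9 in 95.3%, Larp7 in 98.8% and Hexim1 in 99.7%. For the 19204 KAP1 peaks between genes, the shares were 47.0% for Pol II, 69.1% for Cdk9, 87.0% for Larp7 and 89.5% for Hexim1.

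At coding promoters, KAP1 was found where Pol II was found. Of 20136 promoters, 14198 (70.5%) had Pol II, 13004 (64.6%) KAP1, 15120 (75.1%) Larp7, 15849 (78.7%) Hexim1 and 13914 (69.1%) Cdk9. All 5 factors were present at 12021 promoters (59.7%, 59.0 to 60.4) and none at 3679 (18.3%). KAP1 was at 87.2% of promoters with Pol II and at 10.4% of the 5938 without it, a difference of 76.8 points (75.2 to 78.4). The same contrast was 94.9% against 27.6% for Larp7, 98.4% against 31.6% for Hexim1, and 91.0% against 16.8% for Cdk9. Over quintiles of Pol II fold, KAP1 was at 77.7%, 76.5%, 89.7% and 94.7% of promoters in ascending order, and the interval for the highest quintile was 96.9% to 98.0%. Among peaks with a −log10 q of at least 5 the KAP1 difference was 34.2 points, from 35.4% against 1.17%, and with 20000 peaks per list it was 49.3 points.

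**Figure D2:**
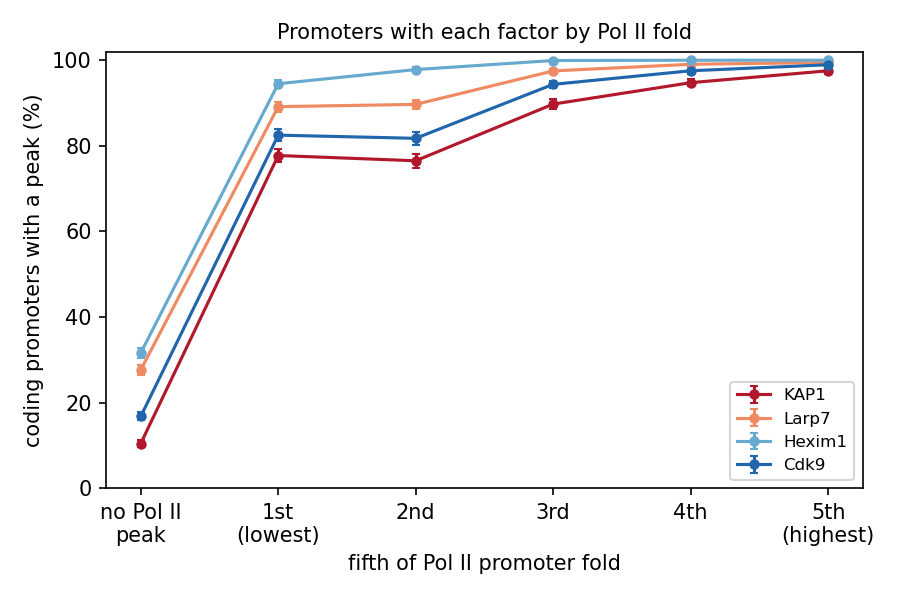
Share of coding promoters (vertical axis, percent) with a KAP1, Larp7, Hexim1 or Cdk9 peak, for the 5938 promoters without a Pol II peak and for quintiles of the 14198 Pol II promoters ordered by Pol II fold (horizontal axis); points are shares with exact 95% intervals. KAP1 goes from 10.4% without Pol II to 77.7% in the lowest quintile and 94.7% in the last but one.

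Among Pol II promoters, those with KAP1 nearly always had the other factors too. Larp7, Hexim1 and Cdk9 were all present at 97.1% of the 12384 Pol II promoters with KAP1 and at 40.4% of the 1814 without it, a difference of 56.7 points (54.4 to 59.1). The gap was widest for Cdk9, at 97.3% against 47.6%. It was 99.3% against 65.2% for Larp7 and 99.9% against 88.0% for Hexim1. At promoters without Pol II, all 3 factors were at 71.1% of the 620 with KAP1 and at 6.07% of the 5318 without it. The difference at Pol II promoters was 54.9 points within deciles of Pol II fold, an alternative added after the data were seen. It was 30.0 points among peaks with a −log10 q of at least 5 and 36.2 points with 20000 peaks per list.

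Pol II inside the gene was slightly more frequent where the promoter had KAP1, and likewise where it had the other 3 factors. In genes of at least 4 kb with a Pol II promoter, a Pol II peak lay in the gene body of 70.1% of the 11395 genes with KAP1 and 61.6% of the 1671 without it, a difference of 8.43 points (5.73 to 11.3). For promoters with Larp7, Hexim1 and Cdk9 together it was 69.8% against 62.0%, a difference of 7.80 points (4.75 to 10.7). The KAP1 difference was 8.07 points within deciles of gene length and 16.1 points when the start of any transcript served as the promoter. Within deciles of promoter Pol II fold, an alternative added later, it fell to 3.33 points (0.412 to 6.34). Peaks over 1 kb from any transcript start gave 9.69 points, and 4.18 points (1.09 to 7.27) within those deciles.

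The strongest KAP1 promoters belonged to genes of varied function. The highest KAP1 fold among promoters with all 5 factors was 11.01, on a peak on chromosome 10 at 127584322 to 127585569 that the divergent genes DHX32, an RNA helicase gene, and FANK1 share. This region was also the strongest promoter site by −log10 p in the Larp7 and Hexim1 lists. Next came ACSL3, which activates long-chain fatty acids (KAP1 fold 10.6), ZNF264 (10.3), UBR3, a ubiquitin ligase gene (10.3), PDCD7 (10.1), MRTFA, a coactivator of serum response factor (9.63), IREB2, an iron regulator (9.57), USP10 (9.55), the kinase gene GSK3A (9.40), MTHFD1L (9.34) and POTEH (9.32). Pol II fold at these promoters ran from 7.91 at POTEH to 142 at ACSL3.

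Some strongly occupied Pol II promoters had no KAP1 peak. The 6 with the highest Pol II fold were the histone gene H2BC5 (175), BSG (157), which encodes basigin, the kinase gene SRC (125), PARP2 (125), a DNA repair gene, the claudin gene CLDN7 (119.8) and the histone gene H2AC12 (117), which shares its peak with H2BC12. Hexim1 was present at all 6, Larp7 at BSG, PARP2, CLDN7 and H2AC12, and Cdk9 at H2BC5, BSG, PARP2 and H2AC12. At H2BC5 a KAP1 peak overlapped the Pol II peak, which is 2954 bp wide, outside the 1 kb window. At BSG, SRC and CLDN7 the annotated 5′ end decides the result. Within 500 bp of it the Pol II fold was only 8.32 at BSG and 8.16 at CLDN7, with no Pol II peak at SRC, and within 2 kb all 3 had KAP1, with folds of 9.05 at BSG, 6.05 at CLDN7 and 5.13 at SRC. PARP2 and H2AC12 had no KAP1 peak within 2 kb. KAP1 promoters without a Pol II peak were led by C8orf48 (KAP1 fold 7.81), ZNF534 (7.73), ITGBL1 (7.33), the chemokine gene CX3CL1 (7.03), ACTL8 (6.71) and ENSG00000267173 (6.59). All 6 had Larp7 and Hexim1, and Cdk9 was missing at ZNF534, ACTL8 and ENSG00000267173.

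The genes of the factors themselves were mostly occupied. TRIM28, which encodes KAP1, had the second highest Pol II peak of the genome by −log10 p, with a fold of 176 on chromosome 19 at 59054892 to 59057033, and carried KAP1 (6.98), Larp7 (6.39), Hexim1 (9.71) and Cdk9 (5.67). HEXIM1 and CDK9 also had all 5 factors, with KAP1 folds of 4.37 and 5.57. At the annotated 5′ end of LARP7 only a Hexim1 peak was found (2.96). The 7SK RNA gene RN7SK, transcribed by Pol III on chromosome 6 at 52860418 to 52860748, had a Pol II peak within 1 kb (13.3), Larp7 (4.41), Hexim1 (6.55) and Cdk9 (4.10), and no KAP1 peak. Of 11 coding members of the list of 7SK snRNP and KAP1 genes, 9 had Pol II and 7 KAP1, led by the splicing factor gene SRSF2 (8.35) and CCNT2 (6.98), a cyclin partner of Cdk9, with HEXIM2 at 6.21. The pair with Pol II and no KAP1, named after their values were seen, was CCNT1 and CBX5.

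Inducible genes carried KAP1 at nearly all promoters that carried Pol II in the full lists. Of 28 immediate early genes, 27 had Pol II, and all 27 had KAP1, at percentile 98.6 among random lists of Pol II promoters. The random lists were not matched for Pol II fold, and in the highest quintile of that fold the interval for KAP1 was 96.9% to 98.0%. Whether the high shares of inducible genes go beyond those of other promoters with as much Pol II was not tested. Examples are the phosphatase genes DUSP6 (KAP1 fold 8.02) and DUSP5 (6.78), the survival gene MCL1 (6.94) and the transcription factor gene SRF (6.65). All 15 Pol II promoters of heat shock and chaperone genes had KAP1 (percentile 93.6), led by the co-chaperone gene BAG3 (7.65), CHORDC1 (6.75), HSPB1 (6.66) and HSPA5 (6.43). All 16 Pol II promoters of Wnt targets did as well (percentile 94.6), including EPHB2 (7.26), SOX9 (6.64), NOTUM (5.90) and ZNRF3 (5.87). The p53 targets had KAP1 at 17 of 18 (percentile 79.96), with TNFRSF10B at 6.89, FDXR at 6.52, AEN at 6.17 and FAS at 5.99, a peak that FAS shares with ACTA2. Among 22 NF-kB inducible genes only 14 had Pol II, and 13 of these had KAP1 (percentile 70.3), such as CXCL1 (5.75), NFKB1 (5.58), NFKBIA (5.43) and BCL3 (5.19). The exceptions, named after their values were seen, were TP53I3 among p53 targets and BIRC3 among NF-kB inducible genes, and ATF3, CRYAB, RNF43, TNFRSF19, CDKN1A and BBC3 had no Pol II peak at the annotated 5′ end. With the start of any transcript as the promoter, Pol II and KAP1 were at all 20 p53 targets and all 28 immediate early genes. KAP1 was then at 15 of 16 heat shock, 17 of 18 Wnt and 15 of 16 NF-kB Pol II promoters. Among peaks with a −log10 q of at least 5, KAP1 was at 35.4% of all Pol II promoters. The shares were 44.4% for immediate early (25.5 to 64.7), 66.7% for heat shock (38.4 to 88.2) and 50.0% for Wnt genes (24.7 to 75.3). They were 64.7% for p53 (38.3 to 85.8) and 4 of 14 for NF-kB inducible genes (28.6%, 8.39 to 58.1). With 20000 peaks per list KAP1 was at 5 of 12 NF-kB Pol II promoters (41.7%, 15.2 to 72.3) against 64.1% of all. The other lists then ran from 74.1% (53.7 to 88.9) for immediate early to 92.3% (64.0 to 99.8) for heat shock. At the stricter threshold only the heat shock and p53 intervals exclude the 35.4% of all Pol II promoters, with lower ends close to it. These intervals treat promoters as independent and are not adjusted for the number of lists, so they do not firmly tell these lists apart. With 20000 peaks no interval of these inducible lists excludes 64.1%.

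The elongation, cell cycle and glycolysis lists were near the share of all Pol II promoters. Transcription elongation genes had KAP1 at 22 of 25 Pol II promoters (percentile 51.4), with NELFCD at 8.01 and ELL at 6.56. Cell cycle genes had it at 22 of 25 (percentile 52.1), with CDC25A at 8.24, MKI67 at 7.41, MCM3 at 6.70 and PCNA at 6.49. Glycolysis genes had it at 13 of 15 (percentile 45.0), with SLC2A1 at 6.91, GAPDH at 6.54, PFKM at 5.99 and ENO1 at 5.40. Imprinted genes had it at 15 of 15 Pol II promoters (percentile 93.8), including INPP5F (6.38), GRB10 (5.86) and ZNF597 (5.78), and DLK1 had KAP1 (5.72) without Pol II. Among peaks with a −log10 q of at least 5, KAP1 was at 4 of 15 imprinted Pol II promoters (26.7%, 7.79 to 55.1), and at 48.0% of elongation, 56.0% of cell cycle and 40.0% of glycolysis ones, against 35.4% of all. With 20000 peaks per list it was at 6 of 8 imprinted Pol II promoters (75.0%, 34.9 to 96.8) against 64.1% of all. The Pol II promoters without KAP1, named after their values were seen, were SUPT6H, CCNT1 and ELL3 among elongation genes, CDK2, PLK1 and AURKA among cell cycle genes, and ALDOC and PGK1 among glycolysis genes.

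Ribosomal protein and replication-dependent histone genes stood apart with fewer KAP1 promoters. Pol II was at 80 of 86 ribosomal protein promoters, and KAP1 at 53 of these 80 (66.3%, 54.8 to 76.4), at percentile 0 among random lists of Pol II promoters. Larp7 was at 66 and Cdk9 at 63 of the 80 (percentiles 0.01 and 0.06), and Hexim1 at 76 (percentile 2.48). The difference from other Pol II promoters was -3.43 points for Hexim1 (-8.43 to 0.529) and -12.3 points for Cdk9 (-21.8 to -3.24). Within deciles of Pol II fold, an alternative added after the data were seen, the Hexim1 difference was -4.53 points (-9.57 to -0.628), an interval that excludes 0. Within deciles of promoter GC content, added in the same way, the difference was -14.2 points for KAP1 (-23.3 to -5.23) and -9.38 for Larp7 (-17.2 to -2.23). It was -7.18 for Cdk9 (-15.5 to 0.691) and -2.62 for Hexim1 (-7.50 to 1.46), intervals that reach 0. The members with the highest KAP1 fold were RPL38 (8.52), RPL13 (8.34), RPL23A (7.86) and RPS20 (7.64). Among those without KAP1, chosen after their values were seen, RPL21 had a Pol II fold of 96.1 and RPS13 of 89.6. Of 66 histone genes 47 had Pol II, and 22 of these had KAP1 (46.8%, 32.1 to 61.9; percentile 0), 31 Larp7 (percentile 0), 32 Cdk9 (percentile 0) and 42 Hexim1 (percentile 0.03). These 47 promoters lie in 4 blocks of 10 Mb and many share peaks, so the exact interval and the random lists, which treat promoters as independent, are too narrow. Within deciles of promoter GC content the histone differences shrank from -40.5 to -16.9 points for KAP1, from -29.1 to -15.9 for Larp7, from -9.08 to -3.94 for Hexim1 and from -23.0 to -3.82 for Cdk9, without intervals. The histone genes H2AC25 and H2BC26 share 1 KAP1 peak (5.30), H3C11 reached 5.55, and H2AC16 had KAP1 (6.12) without Pol II. Among peaks with a −log10 q of at least 5, KAP1 was at 22.5% of ribosomal protein and 6.38% of histone Pol II promoters, against 35.4% of all Pol II promoters, and with 20000 peaks per list the shares were 39.2% and 9.52% against 64.1%.

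**Figure D3:**
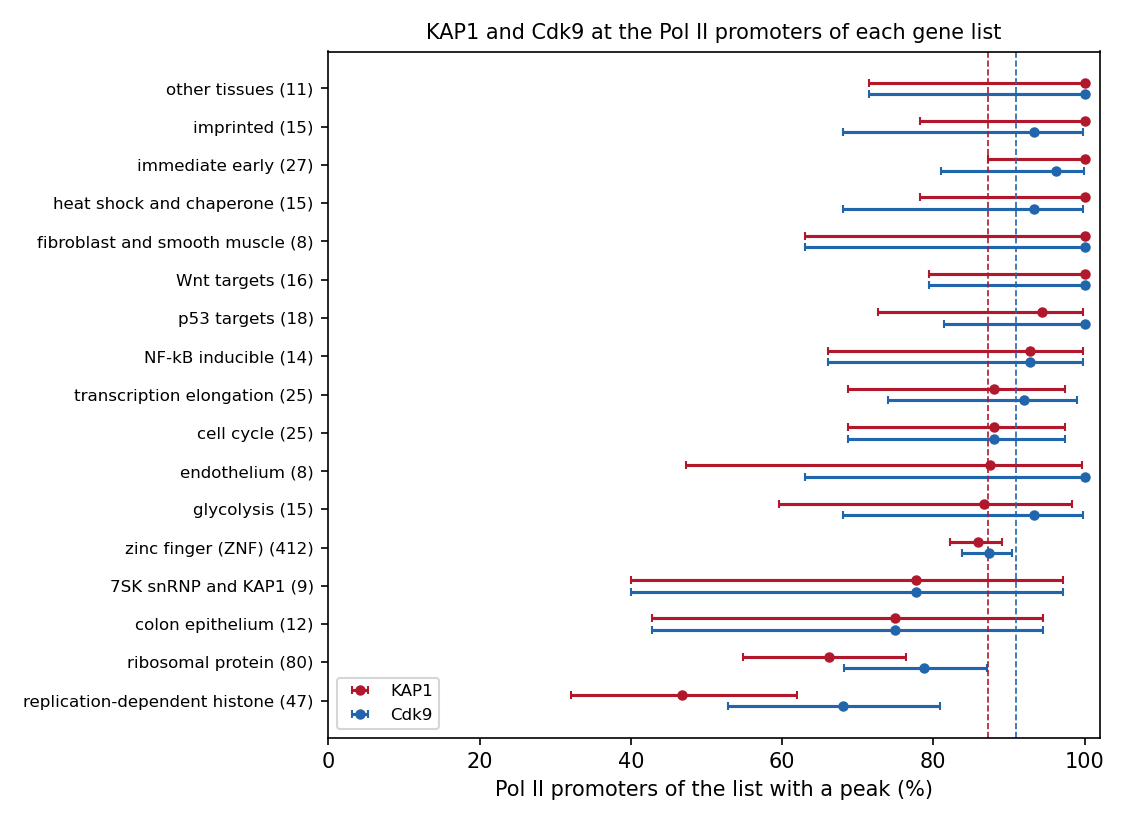
Share of the Pol II promoters of each gene list (horizontal axis, percent; number of Pol II promoters in brackets) with a KAP1 or a Cdk9 peak, for lists with at least 8 such promoters. Points are shares with exact 95% intervals, and dashed lines mark the shares over all Pol II promoters, 87.2% for KAP1 and 91.0% for Cdk9. Ribosomal protein genes (66.3%) and replication-dependent histone genes (46.8%) have the lowest KAP1 shares.

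Zinc finger genes, whose 3′ exons are known KAP1 sites in other cells, carried KAP1 at most of their promoters. Of 508 ZNF genes 388 had a KAP1 promoter peak (percentile 100 among random coding genes), and of the 412 with Pol II 354 did (percentile 21.2 among Pol II promoters). Cdk9 was at 360 of the 412 (percentile 0.66). These percentiles treat promoters as independent, and no interval over genome blocks was computed for the promoters of this list. ZNF264 (10.3), ZNF503 (8.82), ZNF652 (8.67) and ZNF84 (8.23) had the highest KAP1 folds. At the last exon, a comparison added after the data were seen, KAP1 was found in 20.1% of ZNF genes and 20.1% of 19628 other genes, a difference of -0.071 points (-6.25 to 7.21). Within deciles of last exon length it was -1.39 points (-7.69 to 5.26). The list takes every ZNF gene by its symbol, and the last exon was the shortest one annotated to end at the gene's 3′ end. A peak of any fold counted. The equal shares therefore do not show that the known 3′ exon sites are absent in these cells.

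Marker lists of cell types, that of the colon epithelium included, had Pol II at fewer promoters than the median random list. The colon epithelium list had Pol II at 12 of 24 promoters (percentile 1.87 among random coding genes), KAP1 at 10 and Cdk9 at 9. KAP1 was at 9 of its 12 Pol II promoters (percentile 12.5 among Pol II promoters), and the others, named after their values were seen, were EPCAM, CLDN4 and CLDN7. With the start of any transcript as the promoter, KAP1 was at all 14 Pol II promoters of this list. CDX2, a homeobox factor of the intestine, had a Pol II fold of 100.2 and a KAP1 fold of 7.43, CDH1 (E-cadherin) had 97.6 and 6.79, the keratin gene KRT19 had 83.0 and 6.35, and CDX1 had 8.33 and 5.86. The endothelium list had Pol II at 8 of 21 promoters (percentile 0.1), among them SOX18 (72.2), ERG (7.38) and ENG (7.23), and KAP1 was at 7 of the 8, all but CLDN5. TIE1 had a KAP1 peak (4.50) without Pol II. With the start of any transcript, KAP1 was at all 12 Pol II promoters of the endothelium list. Pol II was at 4 of 15 blood cell genes (percentile 0.065) and KAP1 at 2 of the 4, not at CD68 or HBA1, which like CLDN5 are named after their values were seen; SPI1 had a Pol II fold of 5.07 and CSF1R of 5.27, and CD14 had KAP1 without Pol II. Pol II was at 8 of 14 fibroblast and smooth muscle genes (percentile 15.1), all 8 with KAP1. The Pol II fold was 34.9 at ACTA2, on a peak shared with FAS, 6.33 at DES, 6.24 at MYH11 and 5.80 at PDGFRA. Of 26 genes of other tissues 11 had Pol II (percentile 0.135), and all 11 had KAP1, such as SNAP25 (Pol II fold 5.02), NEUROD1 (7.58), INS (5.43) and ACTA1 (20.6). Among peaks with a −log10 q of at least 5, KAP1 was at 0 of 7 Pol II promoters of other tissues (upper limit 41.0%), 0 of 8 of the endothelium (upper limit 36.9%) and 2 of 8 of fibroblast and smooth muscle, but at 5 of 11 of the colon epithelium (45.5%, 16.7 to 76.6), against 35.4% of all Pol II promoters. With 20000 peaks per list it was at 7 of 8 of the colon epithelium (87.5%, 47.3 to 99.7).

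The KAP1 peaks of highest −log10 p lay mostly outside promoters. The first was between coding genes on chromosome 21 at 9825375 to 9827552, over the microRNA genes MIR3648 and MIR3687, with a −log10 p of 72.1 but a fold of 4.15. The DHX32 and FANK1 promoter was second (−log10 p 47.4). The highest KAP1 fold of the genome, 17.2, was on chromosome 12 at 94306 to 95663, between genes. Others lay in introns of PMF1 (chromosome 1, 156186181 to 156186677, fold 3.08), MYO1D (chromosome 17, 31149416 to 31149980, 5.12), GCNT1 (chromosome 9, 79186553 to 79186985, 5.66) and WDR70 (chromosome 5, 37519380 to 37519882, 11.7), and over a long noncoding RNA gene on chromosome 8 at 94845406 to 94847424 (13.3). All 8 overlapped every other list. The chromosome 21, PMF1 and MYO1D sites were also the first 3 of the Cdk9 list. No regions that give signal with any antibody were filtered out here. Peaks of high −log10 p that are in every list may therefore be artefacts and not binding sites of KAP1 or Cdk9. The highest Pol II peaks by −log10 p were at an exon of EEF1A1, which encodes a translation elongation factor and has no Pol II peak at its annotated 5′ end (fold 176), at TRIM28 and at the histone genes H1-4 and H2BC5. The exon label rests on 1 annotated 5′ end per gene, so the EEF1A1 peak may lie at the start of another transcript. Hexim1 was strongest at DHX32 and FANK1 (12.9), in NSFL1C (19.1) and at the SHARPIN and MAF1 promoters (16.8), and Larp7 at DHX32 and FANK1 (9.78), at the chromosome 21 site (2.95) and at TEKT4P2 (13.9).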

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

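Each of the 14 main results was recomputed under its alternatives, 87 values in all, of which the deciles of Pol II fold, the 1 Mb regions, chromosomes 1 to 22 alone and the Pol II peaks away from transcript starts were chosen after seeing the data. Of these, 60 kept their call: all ratios over shifted positions stayed above 1 with 0 of 1000 shifts as high, all differences in percentage points stayed above 0 with intervals that excluded 0, and 3 shares under merging (Cdk9, Pol II and the joint share at KAP1 peaks) stayed in their interval. The other 27 are shares of peaks that left their counting interval. With a −log10 q of at least 5, KAP1 peaks were overlapped by Larp7 in 81.7%, Hexim1 in 94.5%, Cdk9 in 30.2%, Pol II in 86.7% and the first 3 together in 27.5% of cases, and KAP1 overlapped 12.4% of Pol II peaks. Only 8571 KAP1 and 5307 Cdk9 peaks, but 70088 Pol II peaks, reach that threshold, which need not mean the same strength in lists of different layout. With the 20000 strongest peaks these shares were 52.7%, 61.0%, 52.5%, 44.9%, 29.4% and 49.4%. With the middle of each peak they were 66.0%, 63.8%, 64.9%, 61.7%, 42.4% and 46.5%. At 50% overlap they were 88.5%, 90.6%, 72.3%, 62.8%, 70.0% and 56.5%. Merged peaks gave 90.4% for Larp7, 92.6% for Hexim1 and 62.3% for Pol II peaks with KAP1. Of 97 named promoters, 81 had a peak of the same factor at a −log10 q of at least 5 and 89 in a 500 bp window. It was not always the same peak. At BSG and CLDN7 the 500 bp window held a weaker Pol II peak, with folds of 8.32 and 8.16. Beyond the shorter lists, the cause of these moves was not tested. Read depth is unknown, and the absence of a peak is not the absence of a factor. No paired analysis was possible because each antibody has 1 library.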

Other observations

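Of the tests of explanations given here, that at equal Pol II fold for the joint factors was chosen after its result was seen, and that within 1 Mb regions was added last, after the pattern was known. Of 20 small nuclear RNA (snRNA) genes examined, spliceosomal ones and the U7 gene RNU7-1, 16 had a Pol II peak within 1 kb, and of these 14 had Hexim1, 8 Larp7, 6 Cdk9 and 5 KAP1. The U5 genes RNU5A-1, RNU5B-1, RNU5D-1, RNU5E-1 and RNU5F-1 had Pol II folds from 16.2 to 109.8 and no KAP1, Larp7 or Cdk9 peak, and neither did RNU4-2 (43.6) or RNU1-1 (35.9). Within 1 kb of the Pol III genes RNU6-1, RNU6-2, RNU6-9 and RNU6ATAC all 5 factors had peaks, with KAP1 folds of 6.34, 4.72, 5.46 and 5.56. The same held for the Pol II gene RNU4ATAC (4.92). Such windows can also hold promoters of neighbouring genes, which was not checked, so these peaks need not belong to the snRNA genes. Of the other U6 genes, RNU6-7 had KAP1 (4.02) without Pol II, RNU6-8 had Pol II (21.9) without KAP1, and RNU6V had no peak in any list, like the U1 copies RNU1-3 and RNU1-4. The copies of these genes resemble each other, and how reads that fit several copies were treated is not given in the sources used here. Away from Pol II peaks, 9378 of 21926 KAP1 peaks (42.8%, 42.1 to 43.4) had Larp7, Hexim1 and Cdk9 together, against 3.47% after 200 shifts of those peaks. Among imprinted noncoding genes KCNQ1OT1 had all 5 factors (KAP1 fold 4.88), MEG3 had KAP1 (4.89) without Pol II, and H19 had neither. The noncoding genes named here were chosen after their values were seen.

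Peak density was high on chromosome 19 and low on X and Y. Chromosome 19 had 153 Pol II and 81.3 KAP1 peaks per Mb, 5.09 and 4.11 times the genome mean, and chromosomes 17 and 22 had 2.74 and 2.23 times the mean for KAP1. Chromosome X had 3.79 KAP1 peaks per Mb, 0.191 times the mean, and between 0.169 and 0.261 times the mean in the 5 lists. Chromosome Y was lower still, with 30 Pol II and 64 KAP1 peaks, 0.0168 and 0.0544 times the mean.

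Ribosomal protein and histone genes had fewer KAP1 promoters than other Pol II promoters, with differences of -21.1 points (95% interval -31.3 to -11.1) and -40.5 points. For ribosomal protein genes a weaker Pol II signal was excluded as the whole cause, since their Pol II fold was higher (median 74.4 against 39.2) and the difference within deciles of that fold was -25.8 points (-35.1 to -16.8). GC content (median 53.7% against 57.9%) left -14.2 points (-23.3 to -5.23), so it may account for part. KAP1 on the strongest Pol II peak that reached the 1 kb window left -19.3 points (-29.6 to -9.83). That peak is still found through the annotated 5′ end, so a start outside the window is not caught. In a 2 kb window KAP1 was at 75.0% of ribosomal protein Pol II promoters, against 88.4% of all. With the start of any transcript it was at 69.5% against 89.9%. The annotated 5′ end may therefore account for part as well. For histone genes the same tests of Pol II fold, GC content and strongest peak gave -43.7, -16.9 and -42.2 points without intervals. Their 47 Pol II promoters lie in 4 blocks of 10 Mb, under a minimum of 10 set after a first run gave none. Their Pol II fold was higher too (median 63.8 against 39.3), which speaks against a weaker signal, while GC content may account for much of the difference. The test of the 5′ end has the same limit as for ribosomal protein genes, and none of the 3 explanations is excluded by an interval. No biological explanation was tested.

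Larp7, Hexim1 and Cdk9 were together at Pol II promoters with KAP1. Within deciles of Pol II fold 54.9 points (52.5 to 57.4) remained, so the measured fold accounts for little of the difference. A fold from 1 library without a replicate is an imprecise measure of the amount of Pol II. Enrichment that follows only the true amount could therefore leave a difference within deciles, and it is not excluded. Within regions of 1 Mb 54.4 points (51.7 to 57.2) remained, in the 822 regions that hold Pol II promoters with and without KAP1. Differences in gene density or copy number between such regions thus account for little of it, and differences at a smaller scale were not tested. Open chromatin that any antibody enriches cannot be told apart from joint binding: only 0.108% (0.0516 to 0.198) of the decile of Pol II peaks with the highest fold lacked KAP1, Larp7, Hexim1 and Cdk9, which both would give, and neither the input library nor a measure of accessibility was used here. No biological explanation was tested.

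Chromosome X had few peaks. Fewer genes alone could not give this, since 31.6% of its 868 coding promoters had KAP1 against 66.2% on chromosomes 1 to 22, a difference of -34.7 points (-42.1 to -27.6). The shortage was not particular to KAP1. Pol II was at 44.6% of X promoters against 71.8%, a difference of -27.3 points (-34.2 to -22.2). The differences were -27.1 points for Larp7, -24.5 for Hexim1 and -28.7 for Cdk9. A lower copy number of X in this line is a possible explanation that stays open, and the fold cannot decide it. The fold is a ratio over a background that may carry the same copy number, and only promoters with a called peak enter a median. The median Pol II fold at Pol II promoters was 0.705 times that of chromosomes 1 to 22. Its interval (0.450 to 0.908) spans the bound of 0.8 set before the test. At their own promoters the same ratio was 0.862 for KAP1 (0.844 to 0.876), above this bound, and 0.703 for Hexim1 (0.664 to 0.739), below it. It was 0.787 for Larp7 and 0.792 for Cdk9, with intervals that span it. For the same reasons no conclusion on copy number is drawn from these ratios. At X promoters with Pol II all 4 other lists had a deficit within deciles of Pol II fold, of -29.1 points for KAP1 (-39.2 to -20.3), -18.0 for Cdk9 (-28.6 to -10.6), -14.8 for Larp7 (-24.7 to -7.99) and -6.21 for Hexim1 (-15.2 to -0.566). No biological explanation was tested.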
